A study of Mus musculus with 2 samples.

How the data were processed

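Single-cell transcriptomes of subcutaneous RM-1 tumours were measured in 2 libraries, 1 per treatment. How many mice each library holds is not given clearly in the labels. Group and treatment were taken from the labels. The deposited files of each library are a matrix of counts, a list of barcodes and a list of features, and the counts are raw UMIs per gene and barcode, not normalized, per the file headers and the whole-number values. Cell Ranger 7.1.0 wrote the matrices, per the file headers, while the submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10. This difference was not resolved. Libraries were made with a 10x Genomics kit for the 3' ends of transcripts, per the labels. Whether other filters were applied before deposit is not given in the sources used here. Cell Ranger counts reads on the sense strand of annotated genes and discards reads shared between genes, which lowers the counts of near-identical paralogs, and granzyme, Ifit and MHC class I genes have such relatives.

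Both matrices list the same 55357 features. Gene names and Ensembl identifiers were used as the files give them. Positions come from a match of gene identifiers to GENCODE M21 on GRCm38: 52081 of the identifiers matched, as did all 529 genes named or listed. The main genes are Pkmyt1 (ENSMUSG00000023908), Cdk1 (ENSMUSG00000019942), Rsad2 (ENSMUSG00000020641), Ifnb1 (ENSMUSG00000048806), Cxcl10 (ENSMUSG00000034855), S100a9 (ENSMUSG00000056071) and Gdf15 (ENSMUSG00000038508), all protein-coding.

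Cells were kept with at least 500 detected genes and at most 15% mitochondrial UMIs, which removed 132 and 14 barcodes from the vehicle library and 188 and 16 from the RP-6306 library. Doublets were scored per library with the Scrublet method in scanpy 1.11.5 (expected rate 0.08). Its automatic threshold called 0 and 1 cells, which was taken as a failure. Cells scoring above the cut for the highest 8% were removed in each library instead (684 of 9540 and 808 of 10308 cells). Cells tied at the cut were kept, so the share removed was under 8% and smaller in the vehicle library. That choice was made after seeing the data. The retained cells were 8856 and 9500, and tumour-like cells had median depths of 9537 and 9354 UMIs.

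Both libraries were clustered together on log-normalized values with 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. Genes of the fixed response lists that are not also cell type markers were left out of the variable genes. Clusters were named "X-like" from marker lists fixed before the data were examined, as were the gene lists, the rule for named genes, the comparisons and the main alternatives. A cluster took the leukocyte or stromal class with the largest share of its markers at a log2 ratio of 2 or more over all other cells, if these were at least 3 markers and 50% of the list. A cluster without such a class was tumour-like when at least 3 tumour markers stood at a log2 ratio of 0.5 or more over the named clusters. A name was dropped when another class had more markers among the top 10 genes, or when the cluster was shallow and had no own marker there. Leukocytes were clustered again at resolution 2, where a class needed 3 markers and 40% of its list at a log2 ratio of 1 or more, found in most of the cells. The ratio limits, the resolution of the second clustering and the need for most cells to carry the markers were set after the data were examined. Shares of single tumour-like clusters are not interpreted, because genes that define them differed between the libraries and the clusters changed with the settings. Names were rebuilt here from markers and may differ from names given elsewhere.

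Raw counts were summed per class and library and turned into CPM (UMIs scaled by the total of that class and library), computed here. Ratios are log2 of RP-6306 over vehicle on log2(CPM + 1), which understates differences of low genes. Intervals are exact Poisson for a level, exact binomial (Clopper-Pearson) for a share, and exact conditional for a ratio of rates, which has no pseudocount. The interval of a difference of shares was made from both binomial intervals by the square-and-add method. With 1 library per group no test, p-value or standard error was computed, since cells are not replicates.

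Genes were named by size: at least 100 UMIs over both libraries and 50 CPM in the higher one, a log2 ratio of at least 1 in either direction, at most 10 per direction in tumour-like and 5 in macrophage-like cells. Mitochondrial, ribosomal, haemoglobin, unnamed model and receptor variable genes were left out of naming, as were genes under 0.1 of their level in the class with the highest level, which free RNA could supply. For H2-Q7 this applied in macrophage-like cells. Members of lists were named when among the most abundant or the most different at 50 CPM or more. Pkmyt1, Cdk1, Wee1, Ccne1, Ccl5, Cxcl9, Cxcl10, Cd274, Ifnb1, Gzmb, Ifng and Pdcd1 were always given.

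For each of 26 fixed lists the median log2 ratio was taken over members at 10 CPM or more in the higher library, with its percentile among 10000 random lists of equal size matched on mean expression in 20 bins. A percentile describes these 2 libraries only. Lists with fewer than 5 measured genes are not interpreted. The level of 1 member of the type I interferon list is not reported here. Phases were called with scanpy from S and G2/M scores on cells thinned to 2000 UMIs.

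The interval and list code was tested on simulated data. For the tumour-like comparison, run on 3038 genes with 67 genes at 1.5-fold, 67 at 2-fold and 66 at 3-fold, the direction was right for 100% at each size, and the interval covered the true value for 98.5%, 98.5% and 92.4%. Of 100 unchanged lists of 20 genes, 4 fell outside the central 95%, and of lists moved 1.2-fold, 100 of 100 stood above it. For the macrophage-like comparison, run on 3045 genes, the direction was right for 100% at each size, and coverage was 97.0%, 95.5% and 93.9%. There 8 of 100 unchanged lists fell outside and 96 of 100 moved lists stood above. The simulation holds counting error and no variation between animals. Its unchanged lists were drawn from the same genes as the random lists, and its genes varied independently. The shares outside therefore check the code, and not the percentiles of lists whose genes vary together.

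Alternatives were at most 10% mitochondrial UMIs, at least 200 detected genes, doublet calls kept, Leiden resolution 0.5, response genes kept among the variable genes, TMM scaling (edgeR 4.0.16 in R 4.3.3), the mean of per-cell CPM, a pseudocount of 5, a minimum of 10 UMIs without a CPM limit, a list minimum of 50 CPM, thinning to 1000 UMIs and no thinning. Chosen after seeing the data were a log2 ratio of 0.5 as the size, and 5 changes of the cells in a class. These left out a tumour-like cluster led by Nppb and Serpinb2, or macrophage subclusters led by neutrophil genes or of high depth. Others used the joint T-like cluster, or left out a tumour-like cluster led by interferon genes where response genes were kept (for the type I interferon list). The last left out the cell with the most granzyme UMIs, also for single genes and lists in T-like cells. The subcluster of high depth (median 13330 UMIs) was picked by its depth and taken as mixed. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.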

Results

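The series asked what inhibition of the kinase PKMYT1 does to prostate tumours and to the immune cells inside them. PKMYT1 places an inhibitory phosphate on CDK1, the kinase that drives entry into mitosis, and RP-6306 is a small-molecule inhibitor of PKMYT1. RM-1, a mouse prostate cancer cell line, was grown under the skin of C57BL/6 mice, and tumours taken at day 10 of treatment with vehicle or RP-6306 were profiled by droplet-based single-cell RNA sequencing. Each arm held 1 library. The vehicle library had 9686 barcodes with 100815022 UMIs (unique transcript molecules) and a median of 9086.5 UMIs per barcode. The RP-6306 library had 10512 barcodes with 106465655 UMIs and a median of 8932. After filtering, 8856 vehicle cells and 9500 RP-6306 cells were retained. With 1 library per arm no difference could be tested against the spread between animals. Intervals below are 95% intervals that cover counting error only, exact for levels, shares and ratios of levels, and "higher" or "lower" compares these 2 libraries, not the treatments.

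The first comparison asked whether the cellular makeup of the tumours differed between the arms. Tumour-like cells made up 91.0% of the vehicle cells (8063 cells, interval 90.4 to 91.6%) and 90.3% of the RP-6306 cells (8581 cells, 89.7 to 90.9%). Shares of single clusters inside the tumour-like class differed in both directions. A cluster led by Nppb and Serpinb2 held 2.23% of vehicle and 5.38% of RP-6306 tumour-like cells, a difference of 3.15 points (2.57 to 3.74). One led by Krt76 and Ube2c held 14.3% and 11.7%, a difference of -2.54 points (-3.57 to -1.51). The clusters changed with the settings. Where response genes were kept, a cluster with Nppb and Serpinb2 among its leading genes held 403 and 582 cells, against 180 and 462. Cluster shares are therefore not interpreted. Macrophage-like cells were the main leukocytes, at 4.70% (416 cells, 4.27 to 5.16%) and 4.81% (457 cells, 4.39 to 5.26%). T-like cells were 0.497% of vehicle cells (44 cells, 0.361 to 0.666%) and 0.789% of RP-6306 cells (75 cells, 0.621 to 0.989%), a difference of 0.293 percentage points with an interval of 0.0539 to 0.534. Among leukocytes alone, the T-like share was 8.89% of 495 cells and 12.98% of 578 cells, a difference of 4.09 points (0.201 to 7.91). For the T-like subcluster found when leukocytes were clustered alone, it was 8.48% and 11.1%, a difference of 2.59 points with an interval of -1.13 to 6.25. The macrophage-like share of leukocytes was 84.0% and 79.1%, which is -4.97 points (-9.70 to -0.179). Dendritic-like cells made up 0.395% and 0.484% of retained cells, fibroblast-like cells 0.779% and 0.726%, and endothelial-like cells 0.361% and 0.232%. For these 3 classes the interval of the difference included 0. Clusters that met no naming rule held 2.22% of vehicle cells and 2.63% of RP-6306 cells, and the thresholds of that rule were set after the data were seen.

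**Figure D1:**
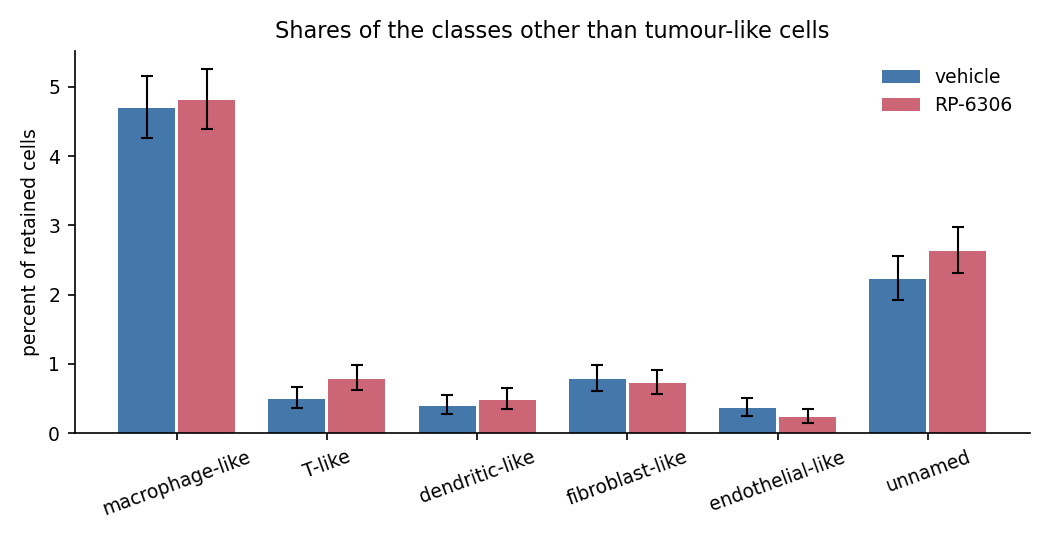
Percent of retained cells (y axis) in each class other than tumour-like cells, for the vehicle library (blue) and the RP-6306 library (red); bars are shares of 8856 and 9500 cells and error bars are exact 95% binomial intervals. The T-like bars stand at 0.497% and 0.789%, and the macrophage-like bars at 4.70% and 4.81%.

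Marker levels set the classes apart. Krt8, an epithelial keratin, stood at 988 CPM (UMIs of a gene scaled to a common total) in tumour-like cells and 104 CPM in macrophage-like cells of the vehicle library. Krt18 went the same way there (569 and 45.6 CPM), but not all tumour markers did. Cdh1 was at 0.0796 CPM in tumour-like and 41.3 CPM in macrophage-like vehicle cells. Epcam was at 3.21 CPM in tumour-like and 11.2 CPM (1 UMI) in T-like vehicle cells. The T-like class was less clean: Krt8 was at 348 CPM there (31 UMIs) in vehicle and 276 CPM (59 UMIs) in RP-6306 cells, against 101 and 61.9 CPM in the T-like subcluster of leukocytes clustered alone. Lyz2, the myeloid lysozyme gene, stood at 5384 CPM in macrophage-like and 8.16 CPM in tumour-like cells of the same library. Neutrophil genes (S100a8, S100a9, Retnlg) led no cluster of retained cells, but they led a subcluster of 24 vehicle and 45 RP-6306 leukocytes that stayed inside the macrophage-like class.

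The second comparison asked how tumour-like cells differed between the libraries. Interferon-stimulated genes were higher in the RP-6306 library. Rsad2, an antiviral enzyme (viperin; chromosome 12, 26442746 to 26456452), was at 24.2 CPM (23.2 to 25.3) in vehicle and 59.4 CPM (57.8 to 61.0) in RP-6306 cells, a log2 ratio of 1.26. Among the 3132 genes with at least 100 UMIs and 50 CPM it was the 1 gene that reached a 2-fold difference; without the CPM limit and with 10 UMIs there were 22. Krt14, a keratinocyte keratin under that limit named after its values were seen, had 13 and 844 UMIs, but 10 RP-6306 cells held 794 of them and 3 cells had 5 or more. Of the 20 measured genes of the type I interferon response list, 18 were higher and 2 lower, and the median log2 ratio was 0.61, above all 10000 random lists matched on expression (percentile 100; central range -0.11 to 0.05). The summed level of the list was 1451 and 1835 CPM, a ratio of 1.26 (1.26 to 1.27). The exceptions, Eif2ak2 and Isg20, turned higher when the mean of per-cell CPM was used.

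Isg15, a ubiquitin-like antiviral protein, was at 59.4 CPM (57.8 to 61.0) and 111 CPM (109 to 113), a log2 ratio of 0.89. Bst2, which tethers virions to the cell surface, was at 83.0 and 143 CPM (0.78). Ifitm3, the most abundant member of the list, was at 1049 and 1184 CPM (0.18). Cells in which the transcripts were found were also more frequent. With every cell thinned to 2000 UMIs, Isg15 was detected in 8.74% of vehicle and 14.8% of RP-6306 tumour-like cells (7972 and 8407 cells), and Rsad2 in 2.82% and 6.05%. No class known to lack these genes was at hand to give a background share.

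**Figure D2:**
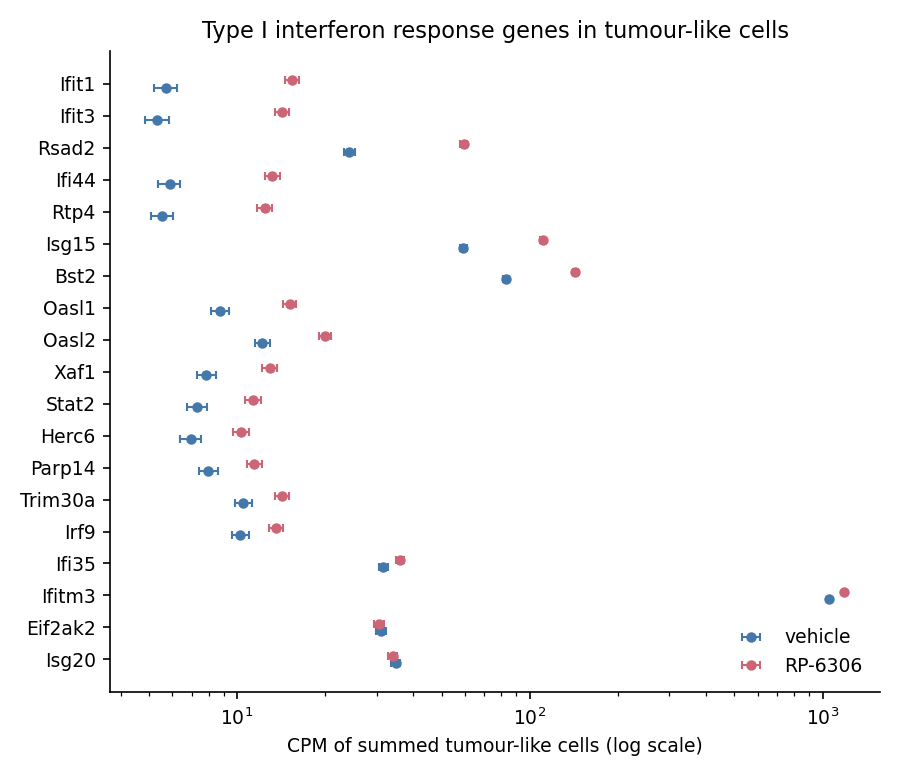
CPM (x axis, log scale) of 19 of the 20 measured type I interferon response genes in summed tumour-like cells of the vehicle (blue) and RP-6306 (red) libraries, with exact 95% Poisson intervals. Rsad2 stands at 24.2 and 59.4 CPM, and Isg20 and Eif2ak2 are the genes shown that were not higher in the RP-6306 library.

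Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774), had 5 UMIs in 2 of 8063 vehicle tumour-like cells and 52 UMIs in 23 of 8581 RP-6306 tumour-like cells. The ratio of the rates was 10.0 (4.04 to 32.2). The UMIs clumped by cell: 1 vehicle cell held 4 of the 5, and 3 RP-6306 cells held 24 of the 52. The interval treats UMIs as independent and is therefore too narrow. The shares of cells with an Ifnb1 UMI were 0.0248% and 0.268% at median depths of 9537 and 9354 UMIs. Macrophage-like cells, at median depths of 3823 and 3530 UMIs, had 0 of 416 and 0 of 457, where 3 counts would be 0.721% and 0.656%. At that lower depth this limits the cells with an Ifnb1 UMI and not the cells that express the gene. Thinned to 2000 UMIs, 0 of 7972 vehicle and 6 of 8407 RP-6306 tumour-like cells kept an Ifnb1 UMI.

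Cxcl10, a chemokine that attracts T cells carrying its receptor (chromosome 5, 92346638 to 92348889), was at 175 CPM (172 to 178) in vehicle and 313 CPM (310 to 317) in RP-6306 tumour-like cells, a log2 ratio of 0.83. The interferon gamma response list had a median log2 ratio of 0.27 (8 genes, 6 higher; percentile 99.99), and of 0.061 when only genes of at least 50 CPM were used. Of its members, Irf1 was at 135 and 133 CPM. The MHC class I presentation list had a median of 0.09 (19 genes, 12 higher; percentile 99.9), with H2-K1 at 2399 and 2730 CPM (0.19) and B2m at 1232 and 1489 CPM (0.27). Tapbp, which loads peptides onto class I molecules, was at 118 and 116 CPM (-0.02). The cytosolic nucleic acid sensing list had a median of 0.09 (14 genes, 9 higher; percentile 99.9), with Ifi204 at 61.4 and 66.0 CPM (0.10) and Aim2, a DNA sensor, at 77.0 and 69.8 CPM (-0.14).

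Ccl5 and Cxcl9 were low in tumour-like cells, at 1.99 and 5.08 CPM for Ccl5 and 0.2503 and 0.988 CPM for Cxcl9. In vehicle cells these were under 0.1 of the level in dendritic-like cells, so free RNA in the droplets cannot be excluded as part of their source. Cd274, which encodes PD-L1, was at 2.104 and 2.74 CPM, a ratio of 1.30 (1.07 to 1.59). It too was under 0.1 of the level in dendritic-like cells, so free RNA may add to it. Yet tumour-like cells held 185 and 250 Cd274 UMIs, against 75 and 95 in macrophage-like and 18 and 43 in dendritic-like cells. Ccl5 had 175 and 463, against 242 and 393 in dendritic-like and 143 and 445 in T-like cells. Lyz2 had 717 and 786 UMIs in tumour-like and 10031 and 9512 in macrophage-like cells. These counts argue against free RNA as the only source of Cd274 and Ccl5. Gzmb had 2 and 18 UMIs, Ifng 2 and 1, and Pdcd1 1 and 1 in the whole tumour-like class.

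The third comparison concerned the cell cycle of tumour-like cells, the process on which PKMYT1 acts. Genes of the G2/M phase were lower in the RP-6306 library: 49 of 50 measured members were lower, 47 with TMM scaling, where Cks1b and Ctcf turned higher. The list's median log2 ratio was -0.27, below all random lists (percentile 0; central range -0.06 to 0.01). Nusap1, a spindle protein, was at 77.6 CPM (75.7 to 79.4) in vehicle and 56.0 CPM (54.5 to 57.6) in RP-6306 cells, a log2 ratio of -0.46. Top2a, the topoisomerase of dividing cells, was at 234 and 184 CPM (-0.35), and Hmgb2, among the most abundant members, at 503 and 466 CPM (-0.11). Summed over the list, the level was 5358 and 4676 CPM, a ratio of 0.873 (0.869 to 0.876). Inside single tumour-like clusters the list's median ranged from -0.41 to 0.57, and it was lower in 6 of 10 clusters.

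Pkmyt1 itself (chromosome 17, 23726336 to 23736735) was at 10.5 CPM (9.81 to 11.2) in vehicle and 8.39 CPM (7.80 to 9.004) in RP-6306 tumour-like cells, a log2 ratio of -0.29. Cdk1 (chromosome 10, 69335146 to 69352938) was at 136 CPM (133 to 138) and 112 CPM (110 to 115), a log2 ratio of -0.27. Wee1, the other kinase that restrains CDK1, was at 22.05 and 23.1 CPM (0.07; lower in the RP-6306 library with the mean of per-cell CPM). Ccne1, the G1/S cyclin E1, was at 17.7 and 19.0 CPM (0.09). The CDK1 control list had a median of -0.24 (16 genes, 11 lower; percentile 0), with Ccna2 at 52.8 and 40.6 CPM (-0.37) and Ccnb2 at 75.9 and 60.8 CPM (-0.32).

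S phase genes had a median log2 ratio of 0.04 (40 genes, 25 higher; percentile 99.9), which turned to -0.0097 when only genes of at least 50 CPM were used. Inside single tumour-like clusters the median was higher in 10 of 10, from 0.03 to 0.63. Pcna, the replication clamp, was at 161 and 170 CPM (0.08), and Uhrf1 at 79.9 and 92.2 CPM (0.20). The summed S phase level was 1882 and 1928 CPM, a ratio of 1.02 (1.02 to 1.03). In phase calls on cells thinned to 2000 UMIs, 22.3% of vehicle (21.4 to 23.2%) and 19.0% of RP-6306 (18.1 to 19.8%) tumour-like cells were called G2/M. The share called S was 18.7% (17.9 to 19.6%) and 22.99% (22.1 to 23.9%), and G1 was 59.0% and 58.0%. Thinning left out 91 vehicle and 174 RP-6306 cells. Without thinning, G2/M was 21.8% and 18.9%, S was 15.9% and 20.8%, and G1 was 62.3% and 60.3%. Thinned to 1000 UMIs, S was 21.9% and 24.0%, a difference of 2.02 points against 4.26 at 2000, G2/M was 24.5% and 21.2%, and G1 was 53.5% and 54.8%. A phase call is relative to the other cells and may also read free RNA, so the calls alone give no rate of cycling.

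**Figure D3:**
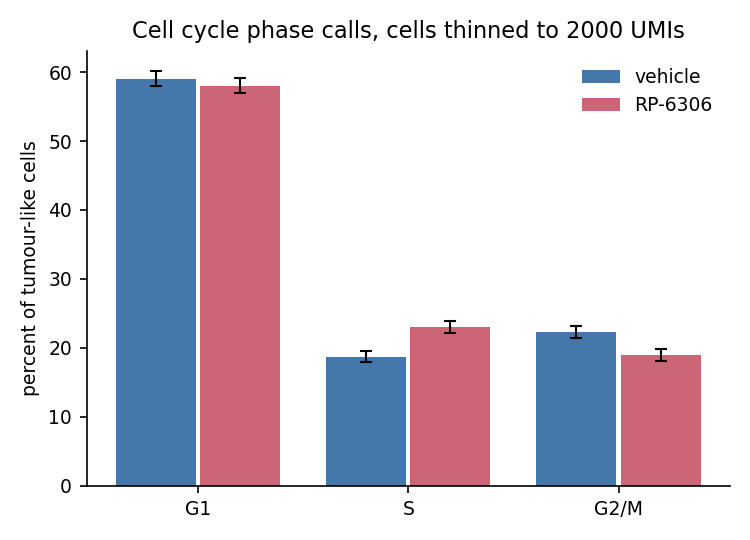
Percent of tumour-like cells (y axis) called G1, S or G2/M after thinning each cell to 2000 UMIs, for 7972 vehicle (blue) and 8407 RP-6306 (red) cells, with exact 95% binomial intervals. G2/M stands at 22.3% and 19.0%, and S at 18.7% and 22.99%.

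Other fixed lists also stood outside their random range in tumour-like cells. The unfolded protein and integrated stress response list had a median log2 ratio of 0.17 (18 genes, 11 higher; percentile 100). Its members went both ways. Higher were Sdf2l1 at 65.7 and 132 CPM (0.99), Manf at 697 and 1011 CPM (0.54), Hsp90b1 at 878 and 1111 CPM (0.34) and Hspa5, the chaperone BiP, at 1409 and 1592 CPM (0.18). Lower were Atf4 at 332 and 292 CPM (-0.18) and Ddit3 at 64.6 and 58.1 CPM (-0.15). The hypoxia and glycolysis list had a median of -0.21 (20 genes, 19 lower; percentile 0), with Bnip3, a mitophagy receptor, at 120.2 and 84.8 CPM (-0.50), Egln3, an oxygen-sensing hydroxylase, at 74.1 and 53.4 CPM (-0.47) and Gapdh at 1737 and 1542 CPM (-0.17). Among lists above the random range by less, the myeloid-attracting chemokine list was at 0.08 (8 genes, 7 higher), with Cxcl2 at 616 and 816 CPM (0.40). The NF-kB target list was at 0.06 (15 genes, 10 higher) and the mesenchymal and matrix list at 0.05 (19 genes, 10 higher, S100a4 at 322 and 221 CPM, -0.54). The p53 target list was at -0.01 (17 genes), the DNA repair and replication stress list at -0.08 (23 genes), the cell death list at -0.00 (15 genes), the checkpoint ligand list at -0.02 (7 genes) and the dissociation stress list at 0.03 (17 genes), all inside it.

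Genes next in size to Rsad2 in tumour-like cells, named after their values were seen, included on the lower side Id1, an inhibitor of transcription factors of the bHLH class, at 737 CPM (732 to 743) and 454 CPM (450.0 to 459), a log2 ratio of -0.70. The homeobox gene Barx2 was at 75.0 and 46.2 CPM (-0.69) and Egr3, an immediate-early transcription factor, at 129 and 79.9 CPM (-0.68). On the higher side stood Hsph1, a cytosolic co-chaperone, at 149 CPM (147 to 152) and 267 CPM (263 to 270.1), a log2 ratio of 0.83, and Vcam1, an adhesion molecule, at 62.8 and 98.2 CPM (0.64).

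**Figure D4:**
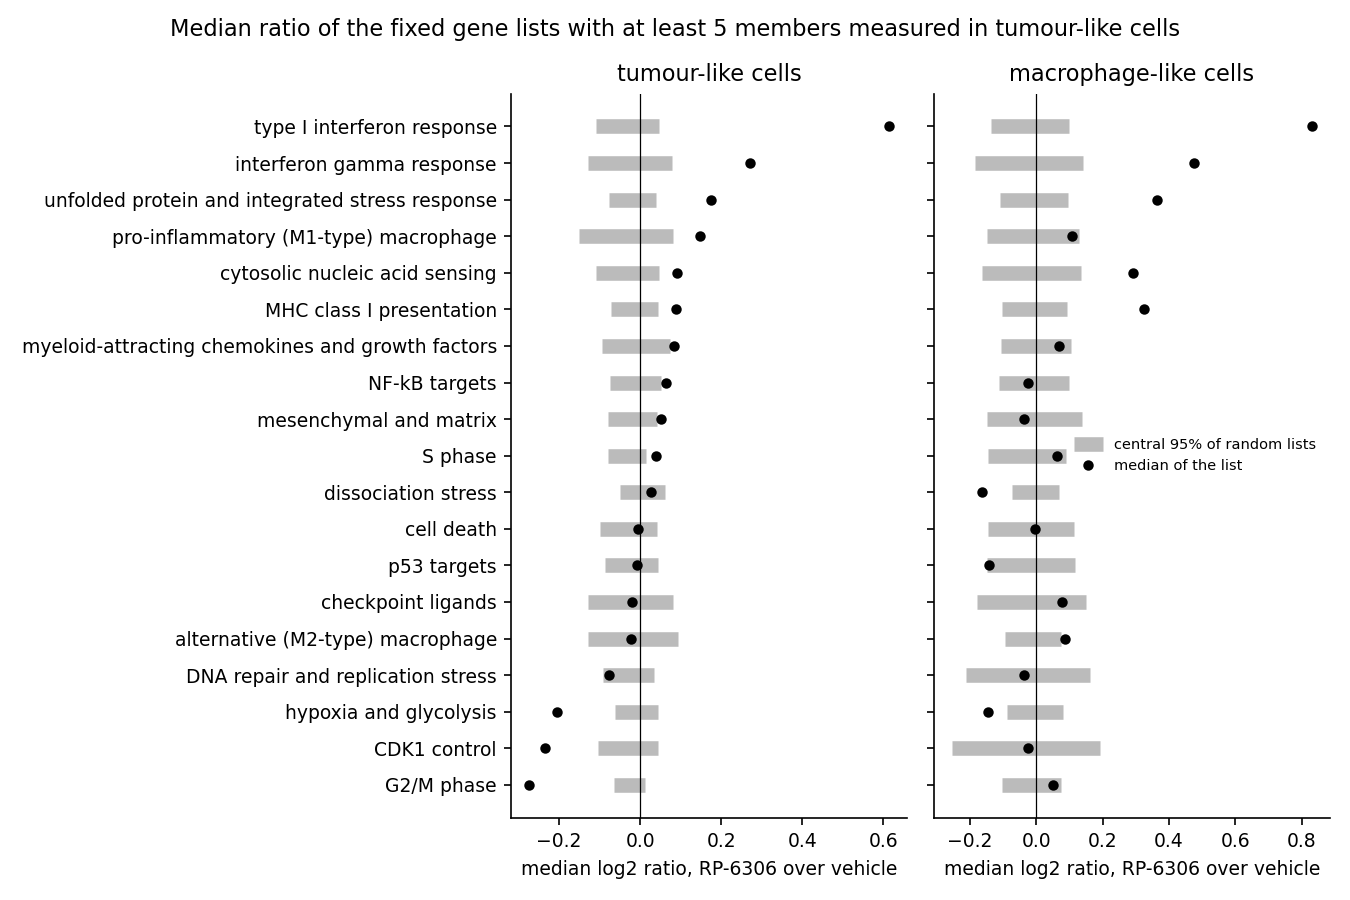
Median log2 ratio of RP-6306 over vehicle (x axis, points) of 19 fixed gene lists in tumour-like (left) and macrophage-like (right) cells, with the central 95% of 10000 matched random lists (grey bars). The type I interferon list stands at 0.61 and 0.83, and the G2/M list at -0.27 in tumour-like and 0.05 in macrophage-like cells.

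The fourth comparison asked how macrophage-like cells, the one immune class with at least 100 cells in each library, differed. All 33 measured type I interferon response genes were higher in the RP-6306 library (32 with the mean of per-cell CPM, where Cmpk2 turned lower). The median log2 ratio was 0.83 (percentile 100; central range -0.14 to 0.10), and the summed level was 3170.3 and 4565 CPM, a ratio of 1.44 (1.39 to 1.49). Isg15 was at 90.2 CPM (77.0 to 105) and 189 CPM (170.2 to 209.8), a log2 ratio of 1.06. Ifi27l2a, an interferon-induced mitochondrial protein, was at 385 CPM (358 to 415) and 766 CPM (727 to 806), a log2 ratio of 0.99. Ifitm3 was at 1712 and 1993 CPM (0.22). Among leukocytes clustered alone, a subcluster led by interferon genes (Cxcl11, Mx1 and Ifit2 among them) held 16 vehicle and 30 RP-6306 cells. These were 3.23% and 5.19% of leukocytes, and the interval of the difference included 0. Only the subcluster led by Ccl8 and Ms4a7 (46 and 59 cells) met the macrophage-like rule there. The list was not compared inside leukocyte subclusters, so a different mix of them stays open.

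In the same cells the interferon gamma response list had a median of 0.48 (18 genes, 15 higher; percentile 100), with Cxcl10 at 308 CPM (283 to 334) and 443 CPM (414 to 474), a log2 ratio of 0.53. MHC class I presentation was at 0.33 (20 genes, 19 higher; percentile 100), with H2-K1 at 1326 and 1684 CPM (0.34), B2m at 1149 and 1493 CPM (0.38) and H2-M3 at 37.6 and 59.6 CPM (0.65). Nucleic acid sensing was at 0.29 (18 genes, 14 higher; percentile 100), with Zbp1, a sensor of Z-form nucleic acids, at 26.3 and 53.8 CPM (1.004). The lymphocyte-attracting chemokine list was at 0.37 (6 genes, 5 higher; percentile 99.9), with Ccl4 at 1675 and 1820 CPM (0.12). Ccl5 had 17 and 66 UMIs, a ratio of 3.81 (2.21 to 6.93), but 1 cell held 32 of the 66, and the level was under 0.1 of that in dendritic-like cells, so free RNA cannot be excluded. Cxcl9 had 35 and 53 UMIs, a ratio of 1.49 (0.952 to 2.35). Cd274 was at 40.3 CPM (31.7 to 50.5) and 50.1 CPM (40.5 to 61.2). MHC class II presentation was at 0.08 (10 genes, 7 higher; percentile 93.6), with Cd74 at 3006 and 3257 CPM (0.12).

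The unfolded protein and integrated stress response list was at 0.37 in macrophage-like cells (16 genes, 10 higher; percentile 100), with Creld2, a secreted endoplasmic reticulum stress protein, at 56.9 and 140 CPM (1.28) and Hspa5 at 1045 and 1365 CPM (0.39). Hypoxia and glycolysis was at -0.15 (20 genes, 18 lower; percentile 0.080), with Slc2a1, a glucose transporter, at 133 and 94.9 CPM (-0.48). The dissociation stress list was at -0.16 (18 genes, 15 lower; percentile 0), with Dnajb1 at 194 and 126 CPM (-0.62) and Hsph1 at 145 and 254 CPM (0.81). The alternative (M2-type) macrophage list was at 0.09 (20 genes, 11 higher; percentile 98.6), with Apoe at 2759 and 3310 CPM (0.26) and Arg1, the arginase of this state, at 574 and 393 CPM (-0.55). That median turned to -0.021 with the mean of per-cell CPM and to -0.043 with the doublet calls kept. The pro-inflammatory (M1-type) list was at 0.11 (15 genes, 10 higher; percentile 95.3), and Il1b was at 2417 and 2527 CPM (0.06). G2/M genes were at 0.05 (48 genes, 26 higher; percentile 92.2), S phase genes at 0.06 (39 genes; percentile 93.6), and Pkmyt1 had 12 and 16 UMIs.

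By the fixed rule of size, 5 nameable genes were highest in macrophage-like cells of the RP-6306 library: Ngp, G0s2, Lcn2, Retnlg and S100a9, which are abundant in neutrophils. S100a9 (chromosome 3, 90692632 to 90695721) was at 201 CPM (181 to 223) and 1076 CPM (1029.6 to 1124), and Ngp at 2.15 CPM (0.585 to 5.50) and 106 CPM (91.8 to 122). Few cells held them: S100a9 UMIs were found in 8 of 416 and 19 of 457 macrophage-like cells, against 0.773 and 4.13 CPM in tumour-like cells. An alternative chosen after seeing the data left out the leukocyte subclusters led by neutrophil genes or of high depth. There S100a9 was at 0.576 and 1.72 CPM and Ngp had 0 and 1 UMIs. The genes at least 2-fold higher then numbered 7 in place of 17, among them Ly6a (1.54 on the log2 scale), Creld2 (1.32), Saa3 (1.29) and Isg15 (1.18).

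On the lower side, Gdf15, a stress-induced cytokine (chromosome 8, 70629393 to 70632456), was at 76.2 CPM (64.2 to 89.8) in vehicle and 22.1 CPM (15.96 to 29.9) in RP-6306 macrophage-like cells, a log2 ratio of -1.74. Matk, a kinase that restrains SRC-family kinases, was at 62.8 CPM (51.9 to 75.3) and 22.1 CPM (15.96 to 29.9), a log2 ratio of -1.46. Without those subclusters the log2 ratios were -1.68 and -1.49.

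The fifth comparison asked about cytotoxic genes in T-like cells. It rests on a T-like leukocyte subcluster of 42 vehicle and 64 RP-6306 cells, under the 100 cells fixed as a minimum, and was chosen after seeing the data. The 9 granzyme genes together, the proteases with which cytotoxic lymphocytes kill, had 116 UMIs in vehicle and 1891 in RP-6306 T-like cells. The ratio of their levels was 10.0 (8.29 to 12.2), but 1 RP-6306 cell with natural killer receptor UMIs and no CD3 UMI held 1587 of the 1891. Without that cell the ratio was 1.75 (1.41 to 2.19). Granzyme UMIs clumped by cell, so the intervals of granzyme levels and ratios in T-like cells, here and below, are too narrow.

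Among cells with a CD3 UMI and no natural killer receptor UMI, granzymes were at 309 CPM (173 to 509) in 29 vehicle cells and 1614 CPM (1324 to 1948) in 44 RP-6306 cells, a ratio of 5.23 (3.03 to 9.67). A granzyme UMI was found in 9 of these vehicle cells (31.0%, 15.3 to 50.8%) and 26 of the RP-6306 cells (59.1%, 43.2 to 73.7%), at median depths of 1302 and 1249 UMIs. In tumour-like cells, which should lack granzymes, the share was 0.335% and 1.36% at median depths of 9537 and 9354 UMIs. Markers of T cell subsets had few UMIs. Over the whole subcluster Cd8a, of cytotoxic T cells, had 3 and 24 UMIs (43.3 and 212 CPM), Cd4, of helper T cells, had 8 and 8 (115 and 70.8 CPM), and Foxp3, of regulatory T cells, had 8 and 5 (115 and 44.2 CPM). Cd8a was found in 2 of 42 vehicle cells (0.582 to 16.2%) and 10 of 64 RP-6306 cells (7.76 to 26.9%). Cd4 and Foxp3 were each found in 6 and 5 cells (5.43 to 28.5% and 2.59 to 17.3%). For all of these markers the intervals overlapped. Granzyme levels were not compared within subsets. Over the subcluster without the cell of 1587 granzyme UMIs, Gzmb was at 317 CPM (199 to 480.2) and 1165 CPM (966 to 1391.5), a log2 ratio of 1.87, and Gzma at 880 and 346 CPM (-1.34). Prf1, which encodes perforin, was at 260 and 404 CPM, a ratio of 1.56 (0.877 to 2.87), against 1044 CPM with the cell. Tnfrsf9, the costimulatory receptor 4-1BB, had a ratio of 1.67 (0.976 to 2.96), Ifng of 1.02 (0.569 to 1.86) and Pdcd1, which encodes PD-1, of 0.946 (0.426 to 2.17). Ccl5 was at 2047 and 3936 CPM, a ratio of 1.92 (1.58 to 2.34). The type I interferon response list had a median log2 ratio of 0.19 in these cells (30 genes, 16 higher, percentile 92.3). In the joint T-like cluster it was at -0.26 (29 genes, 11 higher, percentile 12.0), so its direction turned with the cells taken. In the subcluster 1 vehicle UMI was 14.4 CPM, above the 10 CPM list minimum, so measured members can have few UMIs.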

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

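No test of an explanation was run on the values here, so none was chosen after they were seen. Cxcl10 differed in opposite directions between classes. It was higher in tumour-like cells of the RP-6306 library (log2 ratio 0.83). Higher too were macrophage-like (573 and 841 UMIs), fibroblast-like (34 and 94 UMIs) and endothelial-like cells (50 UMIs in 32 cells and 58 in 22). Cxcl10 was lower in the joint T-like cluster, with 255 UMIs in 44 vehicle cells and 279 in 75 RP-6306 cells. Those were 2863 and 1304 CPM, a log2 ratio of -1.13, so the T-like minus tumour-like difference was -1.97. In this less clean cluster 3 cells of each library held 86 and 90 of these UMIs. In dendritic-like cells Cxcl10 was lower too (62 UMIs in 35 cells and 31 in 46 cells, 416 and 172 CPM, log2 ratio -1.27), a difference of -2.11 from tumour-like cells. There, 3 vehicle cells held 38 of the 62 UMIs and 1 RP-6306 cell held 22 of the 31, so a few cells carry it. With 1 library per arm neither difference was tested.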

How the results depend on the processing

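The alternatives at a log2 size of 0.5, without a cluster or subclusters, with the joint T-like cluster and without 1 T-like cell were chosen after the results were seen. Of 329 values under alternatives, 293 stayed near the main value, 33 moved, and 3 turned in sign from a main value outside its random range or with an interval that excluded 0; near means inside the counting interval for shares and ratios, within 1.5-fold for numbers of genes, and for list medians within a distance set by the width of the random range. These 3 were the S phase list in tumour-like cells, at -0.0097 with a 50 CPM minimum, and the M2-type list in macrophage-like cells, at -0.021 with the mean of per-cell CPM and -0.043 with doublet calls kept. With 200 detected genes, the RP-6306 minus vehicle difference was -2.08 points for tumour-like and 1.66 points for unnamed cells, since a cluster led by Areg, Arc and Ereg then went unnamed and unnamed cells made up 13.4% and 15.1%, against 2.22% and 2.63%. In tumour-like cells, genes at least 2-fold higher numbered 2 with TMM scaling and 22 with 10 UMIs and no CPM minimum, and at a log2 ratio of 0.5 there were 17 higher and 11 lower. In macrophage-like cells there were 88 higher and 59 lower at 0.5, 7 higher and 5 lower without the neutrophil-led and mixed subclusters, and 7 lower with the mean of per-cell CPM. A 50 CPM minimum gave tumour-like medians of 0.83 for type I interferon, 0.061 for interferon gamma and -0.22 for G2/M, and a macrophage-like G2/M median of 0.14, from fewer genes. A pseudocount of 5 gave 0.45 for type I interferon and -0.23 for G2/M in tumour-like cells and 0.71 for type I interferon in macrophage-like cells, as it shrinks the ratios of low genes. In macrophage-like cells the mean of per-cell CPM gave 0.63 for type I interferon and 0.21 for G2/M, and doublet calls kept gave 0.71 for type I interferon. Thinned to 1000 UMIs, the difference in the S share was 2.02 points and in the G1 share 1.30 points, of opposite sign to the main -0.960, whose interval included 0. The granzyme ratio in T-like cells was 6.29 in the joint cluster and 1.75 without 1 cell. Where no construction is named, the cause was not tested. Leiden resolution 0.5 gave no dendritic-like class, and leaving out replicates was not possible with 1 library per arm. In classes of few cells many genes had few UMIs: Cd274 had 9 in T-like cells of each library.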

Other observations

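The tests of leukocyte RNA and of a cluster led by interferon genes in tumour-like cells, the share of granzyme UMIs in 1 cell and the test of cluster mix for G2/M genes were chosen after the values they measure had been seen, and so were the single genes named outside the fixed lists in the next paragraph.

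The type I interferon list was also higher in the small fibroblast-like and dendritic-like classes of the RP-6306 library, with 12 of 30 members lower in the latter; it was not analysed here in endothelial-like cells. In fibroblast-like cells (69 in each library) the type I interferon list had a median log2 ratio of 1.31 (30 genes, 27 higher; percentile 100), with Bst2 at 30 and 101 UMIs. Few cells held much of some members: 3 RP-6306 cells had 49 of the 56 Ifit3 UMIs and 35 of the 65 Isg15 UMIs. For Bst2, 3 cells had 32 of the 101. The unfolded protein list was at 0.72 in these cells (18 genes, 12 higher; percentile 100), with Hspa5 at 1264.5 and 3117 CPM. In dendritic-like cells (35 and 46) the type I interferon list was at 0.43 (30 genes, 18 higher; percentile 99.5) and MHC class I presentation at 0.35 (23 genes, 19 higher; percentile 99.9), with H2-K1 at 1998 and 2901 CPM, while the unfolded protein list was at -0.81 (18 genes, 14 lower; percentile 0). Cd274 in dendritic-like cells was at 121 CPM (71.5 to 191) and 238 CPM (172 to 321). Outside the lists, Hmgcs1 at 177 and 92.8 CPM and Cyp51 at 115 and 68.0 CPM were lower in macrophage-like cells, and Sqle was lower in these (68.2 and 38.5 CPM) and in tumour-like cells (102 and 71.3 CPM). Ahsa1 was higher in both, at 69.9 and 101 CPM in tumour-like and 73.0 and 124 CPM in macrophage-like cells. These are single genes picked by their values, and their pathways were not tested.

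Neutrophil-like cells formed a class of their own only under a lower gene minimum. With at least 200 in place of 500 detected genes, a neutrophil-like class of 33 vehicle cells (0.369%, 0.254 to 0.518%) and 54 RP-6306 cells (0.559%, 0.420 to 0.729%) appeared. Of these, 30 and 46 cells had fewer than 500 genes, and the difference of 0.190 points had an interval of -0.0138 to 0.395.

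Of the lists not yet given, most had few measured genes. In tumour-like cells the pro-inflammatory (M1-type) list was at 0.15 (6 genes, Cxcl10 among them; percentile 99.8) and the M2-type list at -0.02 (5 genes; percentile 46.9). With fewer than 5 genes there were MHC class II presentation (-0.07, 1 gene), lymphocyte-attracting chemokines (0.83, Cxcl10 alone), cytotoxic effector (-0.04, 1 gene), T cell exhaustion (-0.18, 4 genes), naive and memory T cell (0.03, 2 genes), T cell activation (-0.20, 3 genes), and androgen response and prostate identity (0.26, 2 genes). In macrophage-like cells the p53 target list was at -0.14 (18 genes; percentile 2.82), CDK1 control at -0.02, DNA repair and replication stress at -0.04, myeloid-attracting chemokines at 0.07, checkpoint ligands at 0.08, NF-kB targets at -0.02, mesenchymal and matrix at -0.04 and cell death at -0.00, each within its random range. In T-like subcluster cells without the cell of high granzyme levels, the cytotoxic effector list was at 0.64 (17 genes, 14 higher; percentile 100; 1.55 with the cell), the T cell exhaustion list at 0.48 (13 genes; percentile 98.6), the naive and memory list at 0.51 (12 genes; percentile 97.8) and the T cell activation list at -0.01 (14 genes; percentile 59.3). In the joint T-like cluster the last 2 were at -0.07 (percentile 48.3) and -0.43 (percentile 1.96). In the T-like subcluster without the cell of high granzyme levels, G2/M genes were at -1.13 (48 genes, 38 lower, percentile 0). In the joint T-like cluster they were at -0.94 (48 genes, 42 lower, percentile 0). In that subcluster 1 vehicle UMI was 14.4 CPM, above the 10 CPM minimum, so T-like list medians can rest on genes with few UMIs. G2/M genes were at -1.16 in fibroblast-like cells (41 genes, 35 lower, percentile 0). They were at 0.47 in dendritic-like cells (48 genes, 27 higher, percentile 99.9). In dendritic-like cells the CDK1 control list went the other way, at -1.04 (10 genes, 8 lower; percentile 2.12), and Cdk1 had 13 and 5 UMIs, of which 1 vehicle cell held 11. In fibroblast-like cells Cdk1 had 22 and 15 UMIs, of which 3 vehicle cells held 17, so few cells carry the Cdk1 values. The spread over cells was not examined for the other members of the G2/M list.

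The higher type I interferon genes in tumour-like cells of the RP-6306 library may reflect the cancer cells themselves. Leukocyte RNA or doublets would need a macrophage share of 10.8% to supply the gain, but the 10 most abundant macrophage-specific genes gained 0.116% of what that share would bring. A different mix of tumour clusters formed without these genes was argued against by the list's median inside clusters, which was over 50% of the pooled median in 9 of 10. More cells in a tumour cluster led by interferon genes did not account for all of it. In a clustering that kept these genes the median was 0.45 without that cluster and 0.62 with it. That cluster held 99 vehicle and 322 RP-6306 cells, and inside it the list went the other way (median -0.30, 18 of 20 genes lower). A difference between the 2 libraries or mice unrelated to the drug cannot be told apart from the treatment with 1 library per arm, so the interferon difference remains a hypothesis about RP-6306.

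The lower G2/M genes in tumour-like cells of the RP-6306 library were not set by sequencing depth per cell, since the list's median was -0.30 after thinning to 2000 UMIs. Removing doublets, which could take more cycling cells from one library, did not set it either, since the median was -0.28 with doublet calls kept. A different mix of tumour clusters stays open, since inside clusters the list was lower by over 50% of the pooled size in 6 of 10, too few to argue against it. With libraries per arm at 1, a difference between the 2 libraries or mice unrelated to the drug stays open.

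For the higher granzyme genes in T-like cells of the RP-6306 library, 1 cell set most of the size: it held 83.9% of the granzyme UMIs. Without the 3 highest cells of each library the ratio was 2.67 (1.85 to 3.93), so those cells did not account for all of the difference. They were 3 of 42 vehicle and 3 of 64 RP-6306 cells, so a larger share of the vehicle cells was left out. Of the 37 vehicle UMIs left, 1 cell held 13, and the interval treats UMIs as independent. Natural killer cells in the class did not account for all of the difference either. CD3-positive cells without natural killer receptor UMIs gave 5.23, from 15 vehicle UMIs. Leaving out the 3 highest cells cut the granzyme UMIs from 116 to 37 in vehicle and from 1891 to 153 in RP-6306 cells. The level was thus set by few cells in both libraries. Free RNA from the cell of high levels may add to these counts, as tumour-like cells held 28 and 117 granzyme UMIs. Yet a granzyme UMI was found in 0.335% and 1.36% of tumour-like cells, against 31.0% and 59.1% of the CD3-positive cells above. These shares argue against free RNA as the source of most of the granzyme UMIs in those cells. With 1 library per arm, a difference between the 2 libraries or mice unrelated to the drug cannot be told apart from the treatment.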
